A study of Mus musculus with 12 samples.

How the data were processed

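RNA was measured in 12 libraries of wild-type mouse small-intestinal organoids, 3 for each of CA, CDCA, DCA and DMSO. Per the labels' protocols, organoids were kept in a commercial growth medium, cultured for 2 days and then exposed to the acids, poly(A) RNA was selected, second strands were marked with dUTP so that libraries kept their strand, and both ends were sequenced on an Illumina instrument. The authors deposited 1 table per library with a gene symbol and a value in TPM for each of 32587 rows. The unit was inferred from the values, which are not whole numbers and sum to nearly the same total in each library. Salmon 1.8.0 and genome build GRCm39 are named in the submitters' processing notes. The annotation, the strand setting and how transcripts were summed to genes are not given in the sources used here.

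TPM keeps no read depth, so the precision of a single value is unknown and low values carry an error that cannot be stated. TPM values are shares of a total, so a change in abundant transcripts, such as mitochondrial RNA, moves all others. The rows used sum to 889156 to 936841 rather than to one total, with each DCA library (932615 to 936841) above each DMSO library (889156 to 920464), and the rest of the total was not analysed here. Of 4802 rows with a mean TPM of at least 20, 4 were listed at 0 in 1 or more libraries, so an exact 0 can be a failed estimate. Of the rows, 13548 were at 0 in every library, and 116 tested rows had the same values in all libraries as another row. Of the symbols, 31329 (96.1%) were found in the reference annotation used here, which is of another build and served only for names and for transcript length and GC content. No coordinates are given for that reason.

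The plan made before the data were examined was a count model for counts, with limma for normalized values, and as the files hold TPM the second was used. Values were taken as log2(TPM + 1), and the 11952 rows with at least 1 TPM in at least 3 libraries were tested. A linear model with 4 group means over all 12 libraries was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, two-sided, and Benjamini-Hochberg adjustment within each of 6 comparisons at 0.05. A moderated F test over the groups gave the count for any difference. Groups came from the sample labels.

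Gene lists were fixed before the data were examined, 35 lists with 612 distinct genes, of which 14 were found under another symbol and 3 were not found. The 32 lists with at least 5 tested members were tested with camera in limma, which asks whether a list moved more than other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. The counts of called lists were 23 for CA, 13 for CDCA and 23 for DCA against DMSO, 21 for CDCA and 21 for DCA against CA and 19 for DCA against CDCA. With an estimated correlation, the goblet cell markers in CDCA against CA were the only call that held in these 6 comparisons. The median of a list and the direction of its test differed in sign in 1 to 3 lists of each comparison, 0 of them called. Members of a list were counted over all genes and adjusted over the list alone.

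Genes were named by a rule fixed before the data were examined: against DMSO the 12 largest changes in each direction, and between acids the 6 largest, among genes past the threshold with an average log2 value of at least 1 and no overlap between the 3 and 3 libraries. Predicted genes, clone names, identifiers without a symbol and pseudogene symbols were left out of that ranking. Also named were 16 genes chosen in advance (bile acid handling, stem, dividing and differentiated cell markers), of which 1 is not reported here, and up to 4 members with the smallest p of each list described. The text names part of what the rule admits. The bile acid importer Slc10a2 and the membrane bile acid receptor Gpbar1, in that set of 16, were below the filter, at no more than 0.822 and 0.0751 TPM in any library.

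The position of a library was its place on the line from the DMSO mean (0) to the DCA mean (1) in log2(TPM + 1) over the tested genes, with the library itself left out of its group's mean. Shares of TPM were compared with exact two-sided permutation tests. The overlap of calls was set beside 100 simulations of unchanged groups that share controls. Alternatives planned in advance were no filter, median-ratio scaling, a pseudocount of 0.1, the replicate number as a block, a fit of only the 6 libraries compared, an estimated correlation or a rotation test (fry) for lists, and leaving out each library in turn. Added after seeing the data were the removal of 13 mitochondrial and 2 rRNA rows with rescaling, the removal of CDCA replicate 3 and DMSO replicate 1 together, and limma without trend and robust moderation. On simulated data of 11952 genes with 100 changed by 1 log2 unit and 100 by 0.5, the model recovered 94% and 45% for CA, 94% and 44% for CDCA and 94% and 34% for DCA against DMSO, with 7, 7 and 10 false calls among 146, 145 and 138. Here and in the simulations of unchanged groups, genes were drawn independently, with normal errors and the same spread in all groups. The values describe that setting and not the real libraries, where a library can shift many genes together.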

Results

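Expression was measured by RNA sequencing in mouse small-intestinal organoids, epithelial cultures grown from intestinal stem cells, which the labels place in the duodenum. There were 4 groups of 3 libraries each: organoids treated with cholic acid (CA), chenodeoxycholic acid (CDCA), deoxycholic acid (DCA) or the solvent dimethyl sulfoxide (DMSO). The labels give the acids at 50 mmol/L, a dose so high for bile acids that its unit is in doubt, and an exposure of 2 days in one field and 96 hours in another. The libraries hold normalised transcript abundances (TPM) for 32587 gene rows, with totals of 889156 to 936841 TPM. The sequencing depth of each library is unknown, and no counting interval can be given. Between 11464 and 11711 rows reached 1 TPM in a library. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

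The libraries held little RNA of markers of non-epithelial cells. The markers of mesenchymal cells summed to 4.94 to 7.08 TPM in the group means, with vimentin (Vim) the highest at 6.01 TPM in 1 library. Among immune markers, Cd68 was the highest at 4.04 TPM, and among endothelial, glial and neuronal markers, Lyve1 at 3.32 TPM. Mitochondrially encoded RNA made up 17.2 ± 2.74% of TPM in DMSO (mean ± SD, n = 3), 14.0 ± 0.389% in CA, 15.9 ± 2.02% in CDCA and 11.8 ± 0.813% in DCA. In exact two-sided permutation tests against DMSO, p was 0.1 for CA, 0.6 for CDCA and 0.1 for DCA, and 0.1 is the smallest p that 3 against 3 libraries allow. Fold changes are given as log2 fold changes on the log2(TPM + 1) scale, which understates the change of low genes, with 95% confidence intervals (CI). Beside a gene list, the median is that of its tested members' log2 fold changes.

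CA against DMSO asked what the primary bile acid cholic acid changes. Target genes of the farnesoid X receptor (FXR), the nuclear bile acid receptor, rose. Fabp6, the ileal bile acid binding protein, was at 239.9 ± 89.1 TPM in CA and 1.53 ± 0.701 TPM in DMSO (SD, n = 3), a log2 fold change of 6.53 (CI 5.30 to 7.76, limma adjusted p = 0.00466). Both subunits of the basolateral bile acid exporter rose, Slc51b by 3.50 and Slc51a by 2.86 (limma adjusted p = 0.00466 and 0.026). Fgf15, an enterocyte hormone that represses bile acid synthesis in the liver, rose by 1.88 (limma adjusted p = 0.0135). Of the 10 FXR targets listed, 6 passed the filter and were tested. Of these 6, 4 rose over all genes and 5 adjusted over the list alone (median 2.37, camera adjusted p = 8.02e-09, adjusted p = 0.134 with an estimated correlation). Sdc1, 1 of the 6, differed from DMSO by 0.015 with CA, -0.039 with CDCA and -0.13 with DCA, and passed in none of these. Nr0b2, an FXR target that encodes a transcriptional repressor, differed by 0.49 (CI 0.045 to 0.94, limma adjusted p = 0.295).

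Other genes that rose most under CA were Akr1b7, an aldo-keto reductase, by 1.75 (limma adjusted p = 0.0366), and Clec2h by 1.51 (limma adjusted p = 0.0186). Pcx, pyruvate carboxylase, rose by 1.43, and Adh6a, an alcohol dehydrogenase, by 1.42 (limma adjusted p = 0.0135 and 0.0479). The antisense transcript Hnf4aos rose by 1.61 (limma adjusted p = 0.0135), a value that is uncertain because the sources do not say whether quantification used the strand. Glycolysis and hypoxia genes rose as a group, 5 of 22 over all genes and 19 adjusted over the list alone (median 0.29, camera adjusted p = 5.56e-16, adjusted p = 0.134 with an estimated correlation). They included Car9, a carbonic anhydrase induced by hypoxia, at 0.62, Ankrd37 at 0.99 and the glycolytic enzymes Aldoa at 0.34 and Gapdh at 0.45. Of 27 xenobiotic metabolism genes 2 rose over all genes, the glutathione transferases Gstm3 (1.13) and Gstm1 (0.76), and 5 adjusted over the list alone (median 0.45, camera adjusted p = 1.64e-07, adjusted p = 0.413 with an estimated correlation), with a median of 0.69 without DMSO replicate 1. The medians were 0.62 for 25 enterocyte markers, -0.43 for 17 stem cell markers and -0.27 for 25 proliferation genes, with camera adjusted p = 4.51e-07, 2.16e-07 and 4.55e-13 and adjusted p = 0.413, 0.353 and 0.339 with an estimated correlation. Single DMSO libraries moved 2 of these medians by more than 1.5 times. That of enterocyte markers was 0.36 without DMSO replicate 2, and that of stem cell markers -0.67 and -0.21 without DMSO replicates 1 and 3. DMSO replicate 1 lay at 0.331 of the way from DMSO to DCA, past CA replicate 2 at 0.311. No single member of these 3 lists passed the test over all genes. Adjusted over the list alone, 1 enterocyte marker rose, 1 proliferation gene fell and 0 stem cell markers passed. With CDCA replicate 3 and DMSO replicate 1 both left out, chosen after seeing the data, the stem cell markers Lgr5 (-0.65) and Olfm4 (-1.89) passed over all genes (limma adjusted p = 0.0187 and 0.00399). The share of mitochondrial RNA was 14.0% in CA and 17.2% in DMSO.

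In all, 69 of 11952 genes differed between CA and DMSO at a limma adjusted p under 0.05, 68 higher and 1 lower, and 1763 had an unadjusted p under 0.05. The gene that was lower, chosen here after its values were seen, was Akr1d1, a steroid reductase of bile acid synthesis, at 0.536 ± 0.139 TPM in CA and 2.72 ± 0.833 TPM in DMSO (SD, n = 3, log2 fold change -1.26, limma adjusted p = 0.0202). It lost its call without any 1 CA library, without DMSO replicate 2 (limma adjusted p up to 0.121) and with a pseudocount of 0.1. The count depended on single libraries: it was 3, 16 and 2 without CA replicates 1, 2 and 3, 193 without DMSO replicate 1 and 10 without DMSO replicate 2. Without CA replicate 1 or CA replicate 3, 2 of the 12 named genes passed, Fabp6 and Slc51b, which without CA replicate 3 were the 2 genes counted, so each other list member named above lost its call there. Of the 12, 6, 3 and 7 did without CA replicate 2, DMSO replicate 2 and DMSO replicate 3. With all 12 libraries, 6 passed with no filter, 7 with median-ratio scaling and 7 without trend and robust moderation, and 9 passed in a fit of the 6 libraries compared. With mitochondrial and rRNA rows left out and the rest rescaled, an alternative chosen after seeing the data, 40 genes were higher and 6 lower, and 8 of the 12 passed. With CDCA replicate 3 and DMSO replicate 1 both left out, also chosen after seeing the data, the count was 966.

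**Figure D1:**
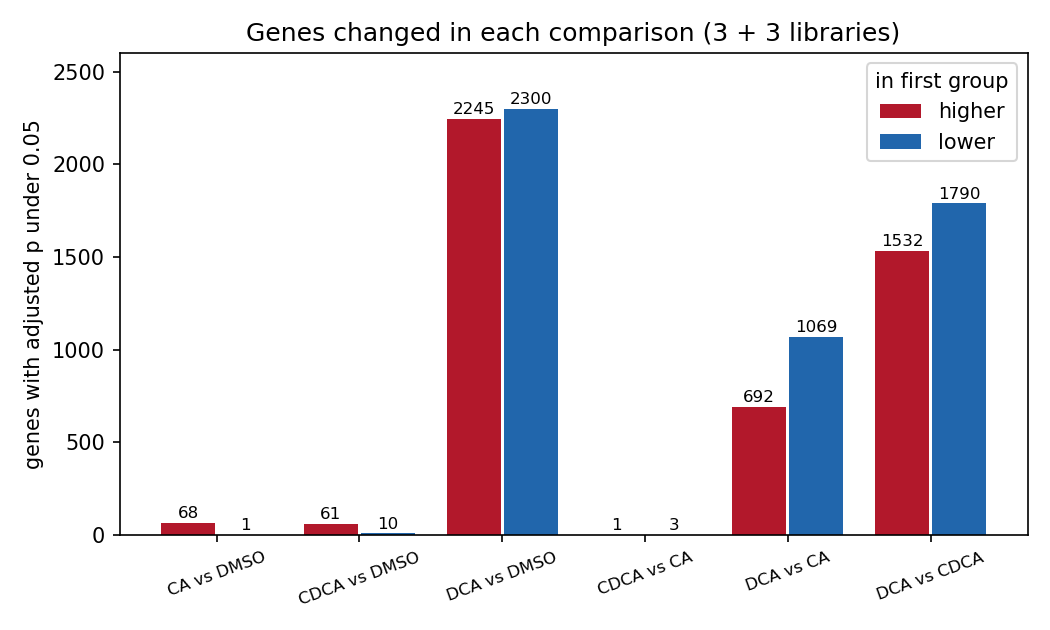
Number of genes with a limma adjusted p under 0.05 in each of the 6 comparisons (vertical axis, genes), as bars for genes higher (red) and lower (blue) in the first group named. DCA against DMSO has 2245 higher and 2300 lower genes, and CDCA against CA has 1 higher and 3 lower.

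CDCA against DMSO asked the same of the other primary bile acid tested. FXR targets rose here too. Fabp6 was at 372 ± 332 TPM in CDCA (SD, n = 3), with 164, 197 and 755 TPM in replicates 1, 2 and 3, against 1.53 ± 0.701 TPM in DMSO (log2 fold change 6.89, CI 5.65 to 8.12, limma adjusted p = 0.000705). Slc51b rose by 3.63, Fgf15 by 2.83 and Slc51a by 2.36 (limma adjusted p = 0.000724, 0.000663 and 0.0492). Of 6 tested FXR targets 4 rose, over all genes and adjusted over the list alone (median 2.59, camera adjusted p = 3.14e-10, adjusted p = 0.0734 with an estimated correlation). Nr0b2 differed by 0.16 (CI -0.28 to 0.61). Cyp24a1, the enzyme that breaks down active vitamin D, was at 5.05 to 6.08 TPM in the CDCA libraries and was listed at 0, 0 and 0.668 TPM in DMSO, a difference of 2.47 in log2(TPM + 1) (limma adjusted p = 9.54e-05).

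The genes that fell under CDCA included 3 hormones of enteroendocrine cells. Gcg, the proglucagon gene, was at 156 ± 16.9 TPM against 312 ± 33.7 in DMSO (SD, n = 3, log2 fold change -1.0, limma adjusted p = 0.000705). Gip was at -0.92 and Sst, somatostatin, at -0.58 (limma adjusted p = 0.00656 and 0.0159). Of 19 enteroendocrine markers 3 fell over all genes and 5 adjusted over the list alone (median -0.14, camera adjusted p = 3.25e-07, adjusted p = 0.155 with an estimated correlation), with a median of -0.22 without DMSO replicate 2. Chga, a general marker of these cells, differed by 0.082 (CI -0.12 to 0.28). The largest fall was in Reg1, a secreted lectin, at 18.5 ± 12.2 against 116 ± 54.7 TPM (SD, n = 3, log2 fold change -2.66, limma adjusted p = 0.0244). Lgals2, a galectin, fell by 0.42 (limma adjusted p = 0.00181). Goblet cell markers fell as a group, 0 of 15 over all genes and 5 adjusted over the list alone (median -0.31, camera adjusted p = 5.37e-12, adjusted p = 0.0734 with an estimated correlation). Genes that rose included Niban1, a stress-responsive gene, by 1.73, Bcl2l15 by 1.52, Pcx by 1.40 and Rin1 by 1.24 (limma adjusted p = 0.000663, 0.00652, 0.00722 and 0.000663). Of 22 glycolysis and hypoxia genes 3 rose over all genes, Car9 (0.52), Vegfa (0.77) and Ankrd37 (0.73), and 14 adjusted over the list alone (median 0.23, camera adjusted p = 2.65e-14, adjusted p = 0.0734 with an estimated correlation). The share of mitochondrial RNA was 15.9% in CDCA and 17.2% in DMSO.

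In all, 71 genes differed between CDCA and DMSO at a limma adjusted p under 0.05, 61 higher and 10 lower, and 1168 had an unadjusted p under 0.05. The count was 41 without CDCA replicate 1 and 44 without DMSO replicate 2, and 22 in a fit of the 6 libraries compared, where 11 of the 21 named genes passed. Of these 21, 12 passed without CDCA replicate 2 or DMSO replicate 3, 16 to 18 without each other library of the 6 and 17 with no filter. In the 6-library fit Slc51a, Reg1, Sst, Lgals2, Bcl2l15, Car9, Vegfa and Ankrd37 lost their calls, and Gip did with CDCA replicate 3 and DMSO replicate 1 both left out. With single libraries left out, Slc51a lost its call without CDCA replicate 2 or any 1 DMSO library, Reg1 without CDCA replicate 1 or 2 or DMSO replicate 1 or 3, and Sst without CDCA replicate 1 or 2 or DMSO replicate 3 (limma adjusted p up to 0.139, 0.0862 and 0.0741). Vegfa lost its call without any 1 CDCA library or DMSO replicate 2 and Ankrd37 without DMSO replicate 2 or 3 (limma adjusted p up to 0.0741 and 0.131). CDCA replicate 3 lay nearer to the DCA libraries than CDCA replicates 1 and 2 did, at 0.522 against 0.101 and 0.171 of the way from DMSO to DCA. The split was 58 higher and 27 lower with median-ratio scaling, and 63 and 22 with mitochondrial and rRNA rows left out.

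DCA against DMSO asked what the secondary bile acid tested changes, and it gave the largest count of the 3 acids. Intestinal stem cell and cell division genes fell. Olfm4, a stem cell marker, was at 16.0 ± 1.8 TPM in DCA and 318 ± 145 TPM in DMSO (SD, n = 3, log2 fold change -4.11, CI -5.27 to -2.96, limma adjusted p = 0.000351). Lgr5, the receptor that marks these cells, fell from 68.0 ± 15.9 to 29.2 ± 2.39 TPM (SD, n = 3, log2 fold change -1.17, limma adjusted p = 0.000895). The Wnt targets Ascl2 and Axin2 fell as well, by 2.05 and 2.22 (limma adjusted p = 0.00106 and 0.00214). Of 17 stem cell markers 15 fell, over all genes and adjusted over the list alone (median -1.30, camera adjusted p = 4.34e-07, adjusted p = 0.293 with an estimated correlation). Of 25 proliferation genes 24 fell by both counts (median -1.02, camera adjusted p = 1.61e-15, adjusted p = 0.236 with an estimated correlation). Among them were Ube2c (-1.02), Cdc20 (-0.85) and Plk1 (-1.17). Mki67, a marker of dividing cells, was at -0.80 (limma adjusted p = 0.00101). Wnt target genes fell in 10 of 13 cases, 11 adjusted over the list alone, while 1 rose (median -0.84, camera adjusted p = 0.000271, adjusted p = 0.293 with an estimated correlation).

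Genes of absorptive enterocytes rose under DCA. Of 25 enterocyte markers 22 rose over all genes and 23 adjusted over the list alone (median 1.35, camera adjusted p = 3.34e-09, adjusted p = 0.301 with an estimated correlation). Among them were Krt20 (1.93), Fabp1, a fatty acid binding protein (1.86), and Lct, lactase (2.12). Alpi, intestinal alkaline phosphatase, was at 125 ± 17.3 TPM in DCA and 42.6 ± 10.1 TPM in DMSO (SD, n = 3, log2 fold change 1.56, limma adjusted p = 0.00155). Fabp6 reached 1411 ± 283 TPM (SD, n = 3, log2 fold change 9.14, CI 7.91 to 10.38, limma adjusted p = 1.81e-05). Slc51b rose by 5.17, Slc51a by 3.88, Fgf15 by 3.31 and Nr0b2 by 0.97. Of 6 tested FXR targets 5 rose by both counts (median 3.60, camera adjusted p = 5.73e-05, adjusted p = 0.236 with an estimated correlation). Nr1h4, the gene of FXR itself, rose by 0.87 (limma adjusted p = 0.00727). Of 27 xenobiotic metabolism genes 24 rose by both counts (median 1.26, camera adjusted p = 5.42e-12, adjusted p = 0.236 with an estimated correlation). They included Gstm3 (2.33), Gstm1 (1.73), Por (1.26) and Cyp24a1, at 5.27 to 6.60 TPM.

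Lipid and sugar metabolism genes rose under DCA as well. Fatty acid oxidation genes rose in 18 of 21 cases, 19 adjusted over the list alone (median 0.70, camera adjusted p = 3.68e-09, adjusted p = 0.236 with an estimated correlation). Acaa1b, a peroxisomal enzyme, was at 2.48. Cholesterol synthesis and uptake genes rose in 17 of 24 cases by both counts (median 0.53, camera adjusted p = 4.74e-09, adjusted p = 0.236 with an estimated correlation). Insig1 was at 1.36 and Hmgcs1 at 0.84. Of 22 glycolysis and hypoxia genes 21 rose and 1 fell by both counts (median 0.62, camera adjusted p = 2.67e-13, adjusted p = 0.236 with an estimated correlation). Secretory cell markers fell. Goblet cell markers fell in 10 of 15 cases and 12 adjusted over the list alone (median -0.38, camera adjusted p = 2.36e-05, adjusted p = 0.236 with an estimated correlation), Clca1 by 1.05 among them. Muc2, the main gel-forming mucin, differed by -0.34 (limma adjusted p = 0.057). It passed without DMSO replicate 2 (-0.45, limma adjusted p = 0.0297), with median-ratio scaling, with the replicate block and with mitochondrial and rRNA rows left out. Paneth cell markers fell in 8 of 15 cases by both counts (median -0.63, camera adjusted p = 0.000761, adjusted p = 0.357 with an estimated correlation), with a median of -0.41 without DMSO replicate 3. Lyz1, lysozyme, was at -1.10. Of 19 enteroendocrine markers 10 fell and 2 rose over all genes, and 11 fell and 2 rose adjusted over the list alone (median -0.40, camera adjusted p = 0.000434, adjusted p = 0.236 with an estimated correlation). Cck (-1.07) and Gcg (-1.12) were among those that fell, and Chga differed by -0.036 (CI -0.23 to 0.16). Mitochondrially encoded genes fell in 10 of 13 cases and 11 adjusted over the list alone (median -0.59, camera adjusted p = 4.8e-05, adjusted p = 0.236 with an estimated correlation). Their share of TPM was 11.8% in DCA and 17.2% in DMSO.

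In all, 4545 genes differed between DCA and DMSO at a limma adjusted p under 0.05, 2245 higher and 2300 lower, of which 363 were higher and 323 lower by at least 1 log2 unit. Other genes far from DMSO were Akr1b7 (3.57), the carboxylesterase Ces1f (3.29), Ggt1 (3.17), the amino acid transporter Slc6a20a (3.13) and Pcx (2.69) on the higher side. On the lower side were Clca3b (-3.04), the interferon-induced Ifitm3 (-2.97), Rgcc (-2.37) and Gast, gastrin (-2.31). Members of families of similar genes, such as Ces1f, Gstm1, Cyp3a25, Lyz1 and the defensins, are uncertain where quantification may split reads between copies. With mitochondrial and rRNA rows left out and the rest rescaled, the median of all genes shifted by -0.15 and the split became 1726 higher and 4116 lower, while it was 2748 higher and 2644 lower with median-ratio scaling and 2538 and 1648 without DMSO replicate 3. Each of the 24 largest named changes, picked for size and adjusted p in these same data, passed under every alternative run.

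**Figure D2:**
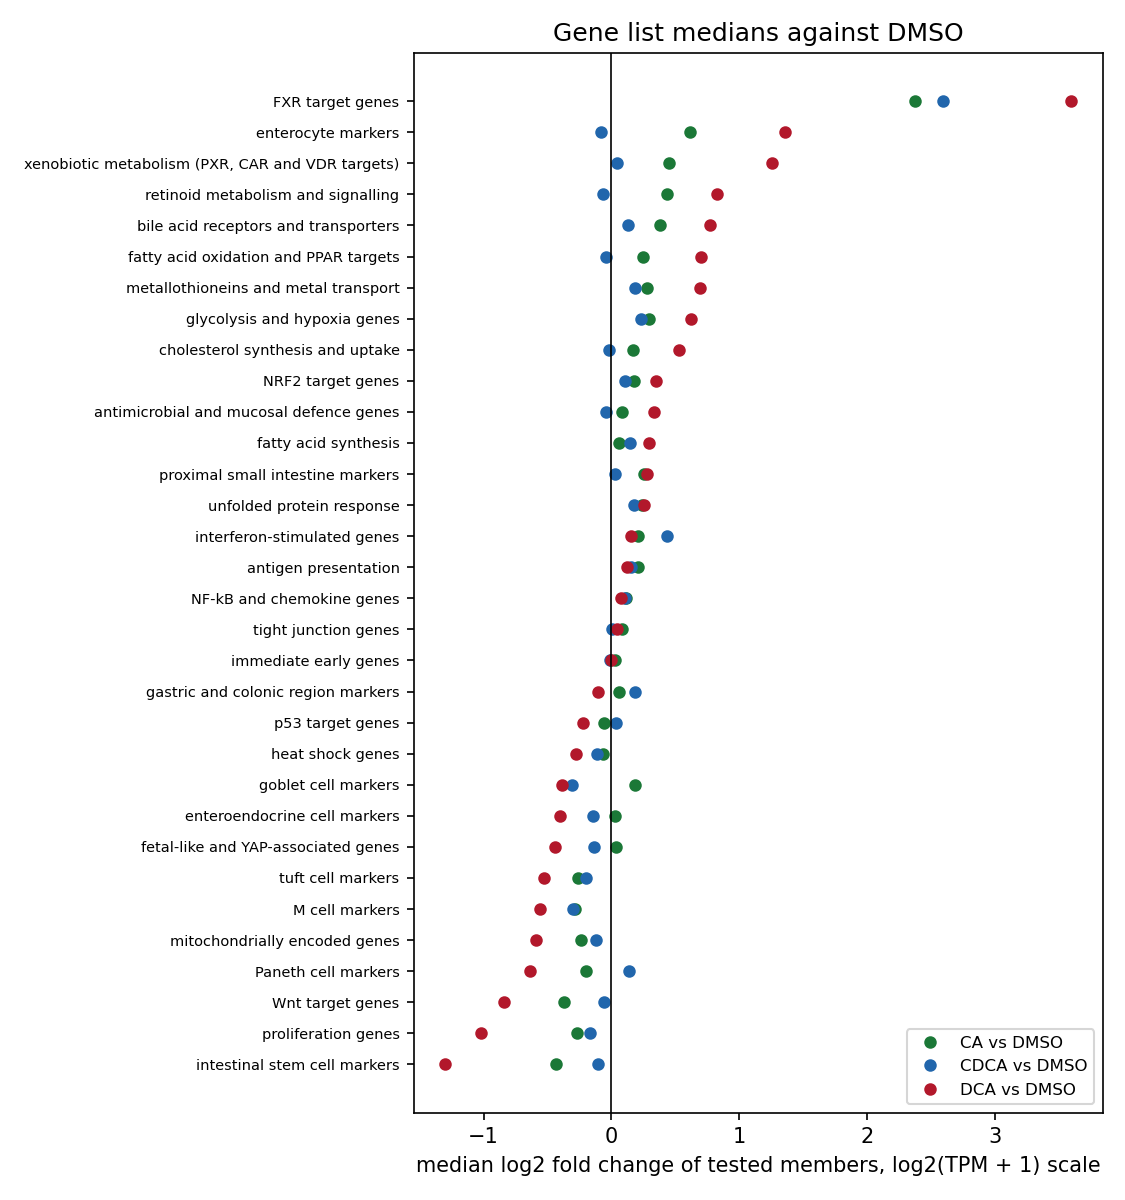
Median log2 fold change on the log2(TPM + 1) scale (horizontal axis) of the tested members of 32 gene lists (vertical axis), for CA (green), CDCA (blue) and DCA (red) against DMSO, ordered by the value for DCA. Enterocyte markers lie at 1.35 and stem cell markers at -1.30 for DCA.

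CDCA against CA compared primary bile acids at one stated dose and time, CDCA lacking the ring-C hydroxyl of CA. In this comparison 4 genes differed at a limma adjusted p under 0.05, 1 higher and 3 lower, and 861 had an unadjusted p under 0.05. Cyp24a1 was listed at 0 in each of the 3 CA libraries and at 5.05 to 6.08 TPM in CDCA, a difference of 2.71 in log2(TPM + 1) (CI 2.31 to 3.12, limma adjusted p = 3.06e-05). Zg16, a goblet cell lectin, was at 46.8 ± 9.30 TPM in CDCA and 146 ± 21.3 TPM in CA (SD, n = 3, log2 fold change -1.63, CI -2.06 to -1.20, limma adjusted p = 0.00659). Gcg differed by -0.93 on the log2 scale, at 156 ± 16.9 against 297 ± 36.7 TPM (SD, n = 3, limma adjusted p = 0.00425), and Lgals2 differed by -0.46 (limma adjusted p = 0.00425). Goblet cell markers were lower in CDCA as a group, 1 of 15 over all genes and 12 adjusted over the list alone (median -0.55, camera adjusted p = 6.9e-20, adjusted p = 0.025 with an estimated correlation). Against DMSO the list was called higher with CA (medians 0.13 to 0.22 with single libraries left out) and lower with CDCA. The call for CA was lost without CA replicate 1 or DMSO replicate 3. Zg16 differed from DMSO by 0.96 with CA and -0.67 with CDCA (limma adjusted p = 0.0536 and 0.221). For Zg16 the CA value lay above DMSO and the CDCA value below it, but neither difference passed. With an estimated correlation, neither list call against DMSO held. Whether the gap between the acids is a fall under CDCA alone is therefore not settled. Muc2, also in the goblet cell list, was at -0.70 in CDCA against CA (CI -0.98 to -0.41, limma adjusted p = 0.163). Against DMSO it differed by 0.37 with CA and -0.33 with CDCA (limma adjusted p = 0.216 and 0.430). With CDCA replicate 3 and DMSO replicate 1 both left out, chosen after seeing the data, Muc2 passed in CDCA against CA (-0.77, limma adjusted p = 0.0130).

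Of 6 FXR targets 0 differed between CDCA and CA over all genes and 1, Fgf15, was higher adjusted over the list alone, with wide intervals: Fabp6 0.36 (CI -0.88 to 1.59), Slc51b 0.13 (CI -0.64 to 0.90), Slc51a -0.50 (CI -1.48 to 0.48) and Fgf15 0.94 (CI 0.35 to 1.53, limma adjusted p = 0.482). Without CDCA replicate 3 these values were -0.33, -0.34, -1.05 and 0.53. With DMSO replicate 1 left out as well, chosen after seeing the data, Slc51a passed at -1.05 (limma adjusted p = 0.0416). The intervals of 11469 of the 11952 genes, 96.0%, lay within 1 log2 unit of 0. That share was 94.6% for CA, 95.6% for CDCA and 82.5% for DCA against DMSO, the last with 4545 genes called. It therefore does not show that CDCA and CA act alike. Enterocyte markers were lower in CDCA by the camera test, 0 of 25 over all genes and 4 adjusted over the list alone (median -0.61, camera adjusted p = 1.66e-16, adjusted p = 0.376 with an estimated correlation). Without CDCA replicate 3 the count of genes was 34, and Zg16 lost its call without CA replicate 1 (limma adjusted p 0.0121 to 0.0596 over the libraries left out), without the filter and with median-ratio scaling. Gcg and Lgals2 lost theirs in a fit of the 6 libraries, and Lgals2 also without trend and robust moderation. The count was 440 with CDCA replicate 3 and DMSO replicate 1 both left out and 7 with mitochondrial and rRNA rows left out, 2 higher and 5 lower.

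**Figure D3:**
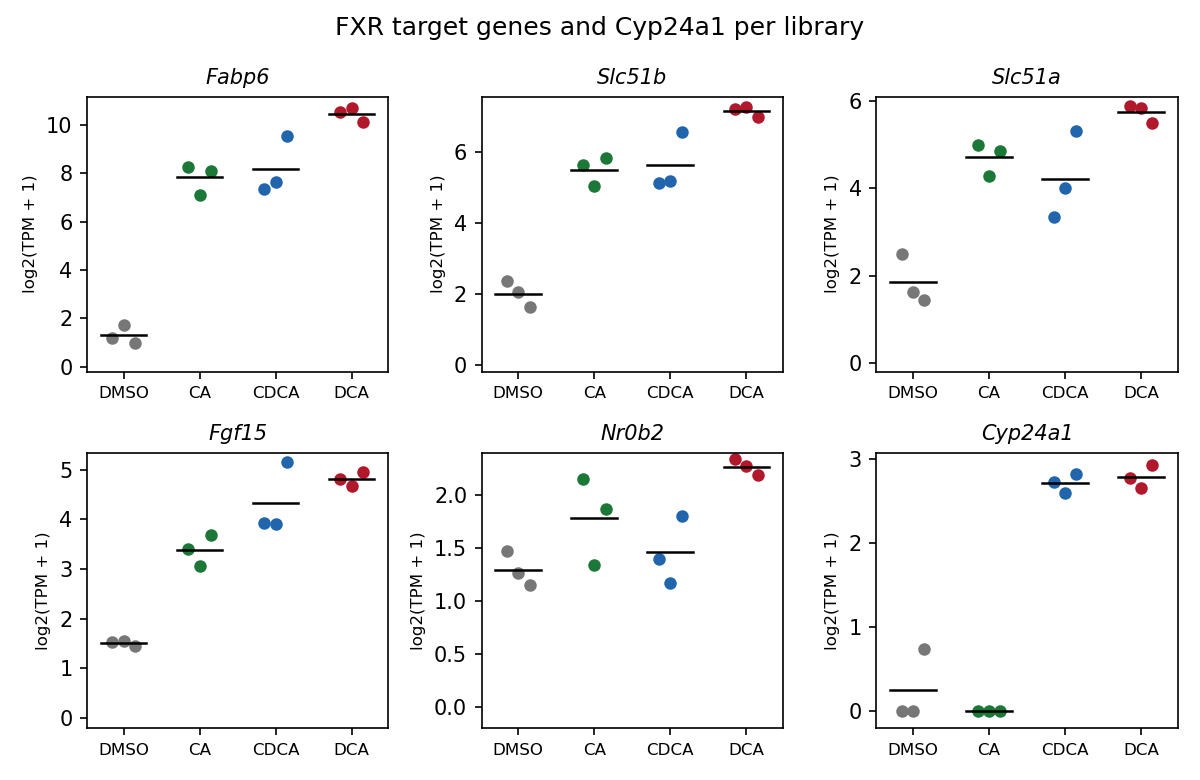
Expression of 5 FXR targets and Cyp24a1 in each library, as log2(TPM + 1) (vertical axis), by group (horizontal axis). Points are the 3 libraries of a group and lines their means, and Cyp24a1 is at 0 in the CA libraries and between 5.05 and 6.60 TPM in those of CDCA and DCA.

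DCA against CA compared acids of which DCA lacks the ring-B hydroxyl, at the same stated dose and time. FXR targets were higher in DCA. Fabp6 was higher by 2.61 (CI 1.38 to 3.85, limma adjusted p = 0.0165), and Slc51b by 1.67 and Fgf15 by 1.43 (limma adjusted p = 0.0126 and 0.00701). Of 6 tested FXR targets 3 were higher, over all genes and adjusted over the list alone (median 1.22, camera adjusted p = 0.000988, adjusted p = 0.212 with an estimated correlation). Slc51a differed by 1.02 (CI 0.039 to 2.01, limma adjusted p = 0.148). Cyp24a1 was listed at 0 in CA and at 5.27 to 6.60 TPM in DCA, a difference of 2.78 in log2(TPM + 1) (limma adjusted p = 2.27e-05). S100g, a calcium binding protein, was at 681 ± 21.9 TPM in DCA and 171 ± 41.6 TPM in CA (SD, n = 3, log2 fold change 2.02, limma adjusted p = 0.00535). Proliferation genes were lower in DCA in 23 of 25 cases by both counts (median -0.75, camera adjusted p = 1.46e-16, adjusted p = 0.211 with an estimated correlation). Olfm4 differed by -2.65 (limma adjusted p = 0.0118). Goblet cell markers were lower in 15 of 15 cases by both counts (median -0.62, camera adjusted p = 2.13e-11, adjusted p = 0.162 with an estimated correlation). Clca1 was at -1.49, Zg16 at -1.34 and Muc2 at -0.71. Against DMSO, Zg16 differed by 0.96 with CA and -0.37 with DCA (limma adjusted p = 0.0536 and 0.155). Its gap between DCA and CA thus includes a CA value above that of DMSO. Enterocyte markers were higher in 6 of 25 cases and 13 adjusted over the list alone (median 0.71, camera adjusted p = 7.49e-09, adjusted p = 0.377 with an estimated correlation). Gast differed by -2.73 (limma adjusted p = 0.000233). The share of mitochondrial RNA was 11.8% in DCA and 14.0% in CA.

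In all, 1761 genes differed between DCA and CA at a limma adjusted p under 0.05, 692 higher and 1069 lower. Leaving out any 1 of the 6 libraries lowered the count by more than 1.5 times, to 1107, 593 and 838 without CA replicates 1, 2 and 3 and 591, 572 and 1017 without DCA replicates 1, 2 and 3. Fabp6 and Slc51b lost their calls without CA replicate 2, DCA replicate 1 or DCA replicate 2 (limma adjusted p up to 0.0690 and 0.0552), and Olfm4 without CA replicate 2 or DCA replicate 2 (limma adjusted p up to 0.0552). With mitochondrial and rRNA rows left out, which shifted the median of all genes by -0.11, 653 were higher and 2072 lower, and with median-ratio scaling 1238 and 1292. In a fit of the 6 libraries compared the count of genes rose instead, and Slc51a passed (limma adjusted p = 0.00720).

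DCA against CDCA compared dihydroxy acids that differ in the position of a single hydroxyl, at the same stated dose and time. Proliferation genes were lower in DCA in 25 of 25 cases by both counts (median -0.91, camera adjusted p = 4.84e-16, adjusted p = 0.219 with an estimated correlation). Enterocyte markers were higher in 23 of 25 cases and 24 adjusted over the list alone (median 1.41, camera adjusted p = 9.61e-15, adjusted p = 0.282 with an estimated correlation). Stem cell markers were lower in 14 of 17 by both counts (median -1.25, camera adjusted p = 5.87e-08, adjusted p = 0.324 with an estimated correlation). Alpi was at 1.85, Olfm4 at -3.36 and Lgr5 at -1.01 (limma adjusted p = 0.00138, 0.00206 and 0.00381). FXR targets were higher in 4 of 6 cases by both counts (median 1.17, camera adjusted p = 0.00892, adjusted p = 0.324 with an estimated correlation). Fabp6 was higher by 2.26 (CI 1.02 to 3.49, limma adjusted p = 0.0145), Slc51b by 1.55, Slc51a by 1.52 and Nr0b2 by 0.81. Fgf15 did not pass, with a difference of 0.48 (CI -0.11 to 1.07, limma adjusted p = 0.209). Without CDCA replicate 3 it passed, at 0.90 (limma adjusted p = 0.000971). Reg1 was at 96.8 ± 16.5 TPM in DCA and 18.5 ± 12.2 TPM in CDCA (SD, n = 3, log2 fold change 2.49, limma adjusted p = 0.00284). Cyp3a25, a drug-metabolising cytochrome, was higher by 2.36 and Arg2, a mitochondrial arginase, by 2.38 (limma adjusted p = 0.000639 and 0.00183). Goblet cell markers did not pass as a group, with 2 of 15 lower by both counts (median -0.14, camera adjusted p = 0.12), and Muc2 differed by -0.016 (CI -0.30 to 0.27). Mitochondrial RNA made up 11.8% of TPM in DCA and 15.9% in CDCA.

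In all, 3322 genes differed between DCA and CDCA at a limma adjusted p under 0.05, 1532 higher and 1790 lower. The count was 2026 and 2022 without CDCA replicates 1 and 2 and 2192 and 2102 without DCA replicates 1 and 2. Slc51a lost its call without any of 5 single libraries (CDCA replicates 1 and 2 and the 3 DCA libraries) and Fabp6 without CDCA replicate 2 or DCA replicate 2 (limma adjusted p up to 0.0898 and 0.0571). Nr0b2 lost its call without CDCA replicate 2 (limma adjusted p = 0.0604). With mitochondrial and rRNA rows left out, which shifted the median of all genes by -0.14, 1315 were higher and 3331 lower. With median-ratio scaling more were higher (2119) than lower (1995), as without CDCA replicate 1 (1107 and 919) and DCA replicate 3 (1290 and 1245).

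Across all 4 groups, 3404 genes differed in at least 1 group by limma's moderated F test at an adjusted p under 0.05, and without DCA replicate 1 or 2 the count was 1996 or 1939. Of the genes called against DMSO, 25 moved in the same direction with CA and CDCA (24 higher, 1 lower), 69 with CA and DCA (68 higher, 1 lower) and 67 with CDCA and DCA (58 higher, 9 lower), and 0 moved in opposite directions. Single libraries moved these overlaps by more than 1.5 times. For CA and CDCA it was 3, 10 and 2 without CA replicates 1, 2 and 3 and 51 and 8 without DMSO replicates 1 and 2. For CA and DCA it was 2, 16 and 2 without CA replicates 1, 2 and 3, 27, 22 and 36 without DCA replicates 1, 2 and 3 and 190 and 10 without DMSO replicates 1 and 2. For CDCA and DCA it was 39 and 44 without CDCA replicates 1 and 2, 44 without DCA replicate 1 and 39 without DMSO replicate 2. Independent lists of these sizes would share 0.347 higher and 0.000837 lower genes, 12.8 and 0.192, and 11.5 and 1.92. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.664, 0.812 and 0.570 for these pairs, where 100 simulations of unchanged groups with the same controls gave 0.49, 0.50 and 0.50. The covariance was 0.0434, 0.114 and 0.0740, and the simulated covariance 0.0147, 0.0149 and 0.0149. The 3 controls cannot be split into parts of at least 2, so part of the excess may come from the shared controls. Genes whose libraries did not overlap between the groups made up 17.0% (CA), 10% (CDCA) and 50.3% (DCA) of those tested against DMSO, and 10.7% (CDCA against CA), 45.6% (DCA against CA) and 48.4% (DCA against CDCA), where chance gives 10%.

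**Figure D4:**
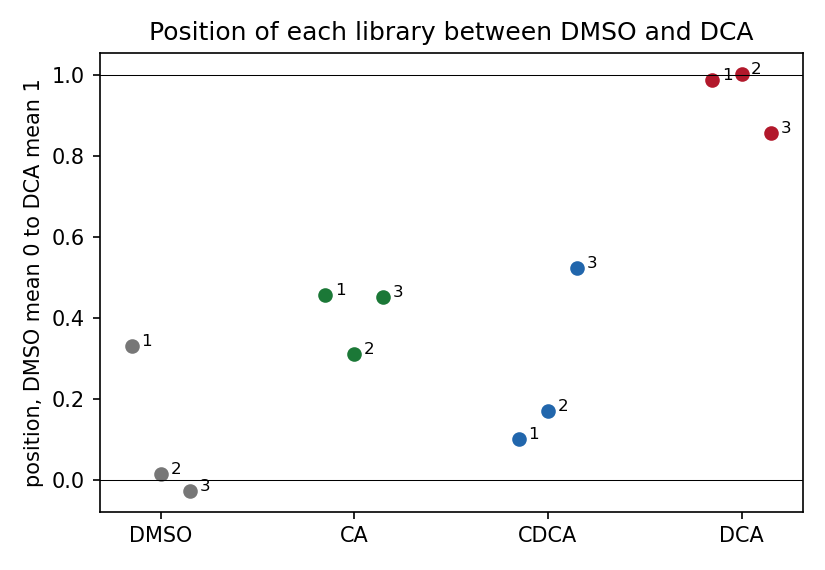
Position of each library (points, numbered by replicate) along the line from the DMSO mean at 0 to the DCA mean at 1 (vertical axis, no unit), by group. CDCA replicate 3 lies at 0.522 and CDCA replicates 1 and 2 at 0.101 and 0.171, and DMSO replicate 1 lies at 0.331.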

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

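The test of vitamin D receptor targets was chosen after the result was seen. For 4 genes the responses to CDCA and CA differed by limma's test of the difference itself: Cyp24a1 by 2.71, Zg16 by -1.63, Gcg by -0.93 and Lgals2 by -0.46 on the log2(TPM + 1) scale. Of the 10 splits of these 6 libraries into 3 and 3, 1 gave as many genes, the real one, with 4 against at most 2 in the others. These 10 splits are too few for a share under 0.05. In a fit of only the 6 libraries compared, 2 of the 4 genes kept their calls.

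Cyp24a1 was at 5.05 to 6.08 TPM in CDCA and 5.27 to 6.60 TPM in DCA, and listed at 0 in CA. In DMSO it was listed at 0, 0 and 0.668 TPM, and CA differed from DMSO by -0.25 (limma adjusted p = 0.578). A general advance along the change from DMSO to DCA would put Cyp24a1 into CA libraries placed above CDCA replicates 1 and 2, and all 3 CA libraries lie above them, while the highest CA value was 0 TPM. If activation of the vitamin D receptor were a candidate explanation, its other targets could rise together. Over 5 of 6 such genes that passed the filter, the median difference between CDCA and CA was -0.15 with an SD of 0.405. Of the 5, 1 was positive and 4 negative (S100g, a calcium binding protein, 0.17, and Cyp3a11, a cytochrome, -0.88). By the criterion first written for this test, a median of 0 or below went against that explanation, and the median was below 0. The explanation is left open here because the median is smaller in size than 0.181, the standard error of a mean over the 5 genes. This second criterion was set after the values were seen. It treats the genes as independent and does not measure the spread between libraries. Other comparisons go both ways. Enterocyte markers, too, were higher in DCA than in CA and in CDCA. A rise of the 5 genes there thus cannot tell receptor activation from that wider change. In DCA against CA the 5 were higher along with Cyp24a1: S100g 2.02, Atp2b1 0.47, Slc30a10 1.56, Cyp3a11 1.37 and Cyp3a25 1.89 (limma adjusted p 0.00218 to 0.0338), where Cyp3a11 lost its call without any of 5 single libraries (CA replicates 2 and 3 and the 3 DCA libraries) and Atp2b1 without any of 4 (CA replicates 2 and 3 and DCA replicates 1 and 2, limma adjusted p up to 0.124 and 0.0877). In DCA against CDCA they were higher too (S100g 1.84, Atp2b1 0.55, Slc30a10 1.71, Cyp3a11 2.25 and Cyp3a25 2.36, limma adjusted p 0.000573 to 0.00512), while Cyp24a1 differed by 0.068 (CI -0.33 to 0.47). In CDCA against DMSO Cyp24a1 rose by 2.47, and by limma 0 of the 5 passed, 1 at an unadjusted p under 0.05. Failed estimation at exact 0 in the 3 CA libraries also stays open, since no read counts were used here, as does a difference between the acids themselves.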

How the results depend on the processing

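The test without trend and robust moderation, the removal of mitochondrial and rRNA rows, and the removal of CDCA replicate 3 with DMSO replicate 1 were chosen after seeing the data. Of the counts recomputed under an alternative, 171 stayed within 1.5 times and 65 did not. Of the values of single genes, 1808 kept their direction and side of the threshold, 188 lost and 18 gained a call and 21 changed sign, and of list values 1513 kept theirs, 259 lost a call and 1 changed direction, by the direction of the test. The median alone changed sign in 4 more cases: Paneth cell markers under CA (0.11 without DMSO replicate 3), fetal-like genes in CDCA against CA (0.00158 with no filter) and, without mitochondrial and rRNA rows, fatty acid synthesis under CA (-0.016) and NRF2 targets in CDCA against CA (0.000638). The 24 largest named changes of DCA against DMSO and the 12 largest of DCA against CDCA passed under every alternative run. Being picked for size, adjusted p and lack of overlap in these same data, they were likely to pass. Fabp6, Slc51a and Nr0b2, also named for DCA against CDCA, lost their calls without single libraries. Except where the alternative itself removes genes or libraries, the cause was not tested. The planned DESeq2 alternative was not run because the files hold no counts, and without mitochondrial rows the mitochondrial list has no value. Unknown depth limits what can be said of low genes.

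With an estimated correlation the counts of called lists were 0 for each acid against DMSO, 1 for CDCA against CA and 0 for DCA against CA and CDCA, and fry called 3 for CA, 4 for CDCA and 26 for DCA against DMSO, 1 for CDCA and 20 for DCA against CA and 22 for DCA against CDCA. With no filter, which adds low genes to the adjustment, CA against DMSO had 26 genes, and the overlaps of CA with CDCA, CA with DCA and CDCA with DCA were 12, 24 and 44. With median-ratio scaling CA had 29 genes and an overlap with DCA of 29, and Muc2 in DCA against CDCA was 0.033. With 6 libraries in the fit CA had 42, CDCA 22, CDCA against CA 2 and DCA against CA 3401. Without mitochondrial and rRNA rows CDCA against CA had 7 and DCA against CA 2725, and Chga in CDCA against CA was 0.019. Without CDCA replicate 3 and DMSO replicate 1, CA had 966 and CDCA against CA 440, where Slc51b was -0.34, Fabp6 -0.33 and Chga 0.076, and Muc2 in DCA against CDCA was 0.061. Without trend and robust moderation CA had 33 and its overlaps with CDCA and DCA were 15 and 33.

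Leaving out 1 library at a time gave 2 to 193 genes for CA, 41 to 86 for CDCA and 3431 to 4896 for DCA against DMSO, 3 to 34 for CDCA against CA, 572 to 1107 for DCA against CA, 2022 to 3943 for DCA against CDCA and 1939 to 3901 for any group. Overlaps were 2 to 51 for CA with CDCA, 2 to 190 for CA with DCA and 39 to 80 for CDCA with DCA. Values that changed direction, none past the threshold in the test reported except the interferon-stimulated list, ranged as follows. In CDCA against DMSO they were -0.00861 to 0.31 for Nr0b2, -0.088 to 0.37 for Nr1h4, -0.33 to 0.065 for Lgr5, -0.17 to 0.11 for Mki67 and -0.000751 to 0.67 for the interferon-stimulated list. In CDCA against CA they were -0.33 to 0.77 for Fabp6, -0.34 to 0.38 for Slc51b and -0.069 to 0.076 for Chga. In DCA against DMSO Chga ranged -0.069 to 0.00998, and in DCA against CDCA Muc2 ranged -0.092 to 0.061.

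The libraries showed no sign of pairing by replicate number. Of 18 pairs with the same number 3 had correlated deviations over 0.1 (-0.378 to 0.109), and 2 of 12 libraries correlated best with their own number. With 3 libraries per group, such correlations cannot exclude a pairing by culture or batch. With the replicate block CDCA against DMSO had 45 genes and the overlap of CDCA with DCA was 43, and the other counts stayed within 1.5 times. Of the named genes 10 of 12 for CA and 16 of 21 for CDCA passed.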

Other observations

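The tests of the ratio of FXR targets and of the share of mitochondrial and rRNA rows under DCA were chosen after the result was seen. Other gene groups moved with the acids. NRF2 target genes, which answer oxidative and electrophilic stress, rose under DCA in 13 of 19 cases and 14 adjusted over the list alone (median 0.35, camera adjusted p = 9.89e-07, adjusted p = 0.236 with an estimated correlation), with Cbr3 at 1.71 and Me1 at 1.71, and in 2 of 19 under CA, 8 adjusted over the list alone (median 0.18, camera adjusted p = 8.25e-05, adjusted p = 0.339 with an estimated correlation), with a median of 0.081 without DMSO replicate 2. In the unfolded protein response 11 of 20 genes rose and 1 fell under DCA, and 12 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.0013, adjusted p = 0.259 with an estimated correlation). Ddit3, a stress-induced transcription factor, rose by 0.51 with CA, 0.77 with CDCA and 1.11 with DCA (limma adjusted p = 0.0343, 0.00181 and 1.81e-05). Scd1, a fatty acid desaturase, rose by 0.77, 1.11 and 2.34 (limma adjusted p = 0.0205, 0.000957 and 5.44e-07). With CA, Ddit3 lost its call without any 1 CA library or DMSO replicate 2 or 3 and Scd1 without any 1 CA library or DMSO replicate 2 (limma adjusted p up to 0.191 and 0.126). Of the 13 fatty acid synthesis genes 1, 2 and 7 rose with CA, CDCA and DCA, or 4, 2 and 7 adjusted over the list alone (camera adjusted p = 0.0381, 0.000187 and 0.000482, adjusted p = 0.559, 0.558 and 0.312 with an estimated correlation). The call of this list for CA was lost without CA replicate 1 or 2 or DMSO replicate 1 (camera adjusted p up to 0.164, median 0.016 to 0.16 over the libraries left out).

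Retinoid metabolism genes rose under DCA in 9 of 9 cases by both counts (median 0.82, camera adjusted p = 1.19e-05, adjusted p = 0.236 with an estimated correlation), with Retsat at 1.25. Metallothionein and metal transport genes rose in 10 of 13 cases, and adjusted over the list alone 11 rose and 1 fell (median 0.69, camera adjusted p = 4.35e-06, adjusted p = 0.236 with an estimated correlation), with Slc30a10, a manganese exporter, at 2.50. Heat shock genes fell in 6 of 11 cases and 8 adjusted over the list alone (median -0.27, camera adjusted p = 0.00978, adjusted p = 0.354 with an estimated correlation), with Hsp90aa1 at -0.84. Tuft cell markers fell in 7 of 11 cases and 1 rose, by both counts (median -0.52, camera adjusted p = 0.0395, adjusted p = 0.339 with an estimated correlation), with Kctd12 at -0.78 and Il17rb at 0.91, and the list lost its call without DCA replicate 1 or DMSO replicate 2 (camera adjusted p up to 0.122). The interferon-stimulated genes were called in CDCA against DMSO with 0 of 17 past the test by either count (median 0.44, camera adjusted p = 0.000497, adjusted p = 0.677 with an estimated correlation), and without CDCA replicate 3 their median was -0.000751. The call was lost without CDCA replicate 3 or DMSO replicate 3 (camera adjusted p up to 0.623), and the median was 0.67 without CDCA replicate 2 or DMSO replicate 1 and 0.29 without DMSO replicate 2.

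CDCA replicate 3 lay nearer to DCA (position 0.522) than CDCA replicates 1 and 2 (0.101 and 0.171). A CA or DMSO library under the CDCA label would leave the genes that set CDCA replicates 1 and 2 apart inside the CA and DMSO range, and 100% of these, only 2 genes (Cyp24a1 and Reg1), lay outside it in CDCA replicate 3, on the same side. That test was planned before its result was seen, but the criterion that let 2 genes count was set afterwards. Mitochondrial RNA made up 15.5% of TPM in CDCA replicate 3, between CDCA replicates 1 (14.2%) and 2 (18.1%). The rRNA rows made up 1.68%, against 0.648% and 0.976%. A lower share of these rows thus does not account for the position. It was 0.517 after they were left out, and with such shares it was likely to change little. Variation between cultures or preparations, or a mixture with a DCA sample, may set this library apart, and no test of these was run.

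The fall of stem cell and proliferation genes and the rise of enterocyte genes under DCA could come from the composition of TPM or from sequence bias. A lower share of mitochondrial and rRNA rows under DCA raises other genes alike, while the proliferation median was -1.02. With these rows left out, the enterocyte median was 1.25, against 1.35 before. These values argue against that share as the whole cause of either part. Log2 fold changes followed transcript length and GC content little (Spearman's correlation -0.045 and 0.010). With these trends removed, which moved 3.43% of genes by over 0.1, the gap between the enterocyte and proliferation medians was 2.33, against 2.38 before, which argues against length and GC content as the whole cause. A change in the mix of cell types and a change of expression within cells were not separated, and a difference in growth or harvest between cultures stays open.

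A hypothesis from these data is that FXR targets reach more of their DCA response with the primary acids than other DCA-responsive genes do. Over the 5 FXR targets called under DCA, the median ratio of the log2 fold change with CDCA to that with DCA was 0.701, against 0.216 over 4540 other genes called under DCA, above 99.85% of 10000 random lists of the same size, with 4 of the 5 above that median and Nr0b2 below it at 0.168. With CA the ratio was 0.676 against 0.376, above 99.74%, with 5 of 5 above. The test restates the pattern that prompted it. The lists were not matched on expression or size of change, and the ratio may depend on both, as it may on the shared DMSO libraries.

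Splits of the samples were refitted for each comparison. For the 6 comparisons of 3 against 3, 1 of 10 splits gave as many genes, the real one, and 10 are too few for a share under 0.05. The real counts and the highest of the other splits were 69 and 1 for CA, 71 and 2 for CDCA and 4545 and 0 for DCA against DMSO, 4 and 2 for CDCA and 1761 and 1 for DCA against CA, and 3322 and 1 for DCA against CDCA. For any difference among the 4 groups, 1 of 100 splits, the real one, gave as many as 3404 genes, with 2521 the highest of the others, so that a random grouping of these libraries is excluded at a share under 0.05. The test treats libraries as exchangeable, so it cannot exclude a difference in culture or harvest between the groups.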
